A study of Homo sapiens with 4 samples.

How the data were processed

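The series holds 4 RNA-seq libraries of MDA-MB-231 cells, 2 transfected with scrambled siRNA and 2 with METTL14 siRNA, from total RNA sequenced as single-end reads of 100 bases per the labels' protocols. Each library came with 1 deposited table of raw counts per gene symbol, made by the authors and not normalized. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8b, HTSeq without a version and the genome builds hg19 and GRCh37. The annotation, the strand setting and the role of each tool are not given in the sources used here.

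Lines that name no gene were left out of library sizes and tests. Reads outside any gene were 13.3% to 13.8% of all lines' reads per library, reads at more than 1 place 14.2% to 14.7% and ambiguous reads 0.882% to 0.938%. The remaining 71.0% to 71.1% were assigned to 23228 genes. Assigned reads were 71592070 and 66825654 for scrambled siRNA replicates 1 and 2, and 68063933 and 64969832 for METTL14 siRNA replicates 1 and 2. The 10 most abundant genes took 2.48%, 2.71%, 3.65% and 3.96% of them. At this depth 3 counts, the floor used for a gene that is not detected, correspond to 0.0416 to 0.0477 CPM, a figure that covers counting error only.

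Groups were taken from the libraries' titles. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The libraries of a group were checked for 1 library deposited a second time. A chi-square comparison of their counts gave 21.1 per degree of freedom for scrambled siRNA and 59.7 for METTL14 siRNA. Its reference is counting noise alone, which any separately prepared libraries exceed, so it does not tell technical from biological replicates. With 2 against 2, an exact two-sided permutation test of 1 gene cannot give a p under 0.333, so genes were tested only with a model fitted across all genes.

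Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its default minimum of 10 counts (15 in total), which left 14340. TMM factors of 1.01, 0.993, 1.03 and 0.968 were used, and the groups were compared with the quasi-likelihood F test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. The biological coefficient of variation was 13.2%. Standard errors are the log2 fold change divided by the square root of the F statistic. The median log2 fold change over all genes was -0.0085, and CPM in the text are TMM-scaled.

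The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are METTL14, the 4 genes the series names, members of the m6A lists past the threshold, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM, and up to 3 members of every other list by smallest adjusted p, or up to 2 by smallest unadjusted p where none passed. METTL3 and PDGFB were named in addition. Symbols that are only clone or locus names were passed over. Some genes that meet the rule are not reported here.

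The 31 lists held 825 entries, of which 797 matched a gene symbol or older symbol in the files. Mitochondrially encoded mRNAs matched 0 of 13 and are not analysed here, so 30 lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over lists by Benjamini-Hochberg. With it 7 lists passed an adjusted p of 0.05, and 0 passed with an estimated correlation. The latter rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. In it 1 list, the mesenchymal genes, had an unadjusted p of 0.0479, against 5.49e-05 with the preset, although its estimated correlation was only -0.013. A miss there therefore does not show whether correlation between genes accounts for a list's result. The directional test of fry passed 2 lists, the study-named genes and the TGF-beta pathway components, and its mixed test 25. Neither form of fry compares a list with other genes. Besides these 2 and the list not analysed, the lists are m6A writers, m6A erasers and readers, TGF-beta targets, mesenchymal, epithelial, G1/S, DNA replication, mitosis, p53 targets, apoptosis, interferon-stimulated, NF-kB and inflammatory, immediate early, amino acid and ER stress, cholesterol synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, histones, small structured RNAs, long nuclear RNAs, RNA interference machinery, integrins and matrix, Wnt targets, YAP/TAZ targets, and luminal, fibroblast and blood cell markers.

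The gene test was tested on simulated data in 3 runs, each drawn for the 14340 genes from the libraries' own means, sizes and dispersions with 200 genes changed. It called 36.7% of genes changed 1.5-fold, 76.5% of those changed 2-fold and 92.9% of those changed 4-fold, and 7.06% of its 439 calls carried no planted change. Of 60 simulated lists without a change 0 were called, and all 3 lists shifted 1.5-fold were. Each run changed a far smaller share of genes than the 20.8% called in the data. An adjusted p depends on that share, so the percentages of genes called hold for the simulated share only. Simulated genes were drawn independently of each other. These numbers therefore do not cover lists whose genes vary together, such as the mitosis genes (estimated correlation 0.585).

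Alternatives were RLE and upper-quartile factors, library size only, DESeq2 1.42.0, limma-voom, edgeR without its legacy setting, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, adjusted p of 0.01 and 0.1, a test against a fold change of 1.5, and other forms of the list test. With a library left out, its group keeps 1 library, which is assumed to vary like the other group. Chosen after seeing the data were offsets for each library's trend on GC content (loess of log2 CPM on transcript GC), with and without the block, and counts without genes that carry a given 3′ UTR heptamer.

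For the closing section, the longest annotated 3′ UTR of each gene was taken from GENCODE 29, whose build is not the authors', so no coordinates are given. Of the tested genes, 12950 (90.3%) had an annotated 3′ UTR, with the shortest ones left out. All 16384 heptamers were scanned for enrichment by a hypergeometric test with Bonferroni correction, with every tested gene that has a 3′ UTR as background. METTL14 was kept in the scan, and its own 3′ UTR holds neither GTTGTAC nor GAATATA. Odds ratios were adjusted for log2 3′ UTR length and GC content in a logistic model (statsmodels 0.14.6, scipy 1.17.1). On simulated sets among the 12950 genes, the scan ranked the planted heptamer first in 10 of 10, and 0 of 10 random sets passed.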

Results

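RNA was sequenced from MDA-MB-231 cells, an established human breast cancer line of mesenchymal, triple-negative character, after transfection with a small interfering RNA (siRNA) against METTL14 or with scrambled siRNA. METTL14 is the RNA-binding partner of METTL3 in the complex that writes N6-methyladenosine (m6A) on messenger RNA. There were 4 libraries, 2 per group, and the METTL14 siRNA cells were taken 48 h after transfection. The labels give no time for the scrambled siRNA cells, so a difference in harvest time could not be told apart from the siRNA. Each group is represented by n = 2 libraries throughout. Reads assigned to genes totalled 71592070 and 66825654 in the scrambled siRNA libraries and 68063933 and 64969832 in the METTL14 siRNA libraries. The files held 23228 genes, of which 14340 had enough counts to be tested.

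The design implies 1 comparison, which asks how the transcriptome of these breast cancer cells differs after METTL14 silencing. METTL14 itself came to 47.2 and 45.5 CPM (counts divided by the TMM-scaled library size) in the scrambled siRNA libraries and to 2.39 and 3.45 CPM in the METTL14 siRNA libraries. Its raw counts were 3405 and 3017 against 168 and 217. Its log2 fold change was -3.99 (SE 0.20), a 15.9-fold lower mean, with an adjusted p of 0.000123 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries' labels and the level of the targeted gene thus go the same way in all 4 libraries.

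At an adjusted p under 0.05, 1524 genes were higher and 1462 were lower after METTL14 siRNA, of which 510 and 427 changed by at least 2-fold. Of the genes with a mean of at least 5 CPM, the largest rises were in ANO2, a calcium-activated chloride channel gene (log2 fold change 3.28, SE 0.20, adjusted p = 0.00015), and in LAMA1, which encodes a laminin alpha chain (2.86, SE 0.15). They were followed by CLIC5 (2.78), IL13RA2, a decoy receptor for interleukin 13 (2.66), AADAC (2.62), SEMA3D (2.57), DUSP1, a phosphatase that switches off MAP kinases (2.52), the growth factor gene PDGFD (2.49), RELN (2.47) and RPL13AP20 (2.35). The largest falls were in UCN2, a peptide hormone of the corticotropin-releasing family (-4.41, SE 0.18, adjusted p = 7.47e-05), METTL14, and KLF2, a zinc finger transcription factor (-3.33, SE 0.24). CALM2, a calmodulin gene, fell by 3.13 on the log2 scale (SE 0.17), from 933 and 1069 to 97.4 and 130 CPM. RHOB, a small GTPase, fell by 3.13 as well (SE 0.13), and COL7A1, GGCX, FBN1 and the sheddase ADAM10 had log2 fold changes of -2.45, -2.30, -2.15 and -2.13. The METTL14 siRNA libraries lay apart for COL7A1, at 3.83 and 1.19 CPM against 14.6 and 12.9 (SE of the log2 fold change 0.45). COL7A1's log2 fold change was -3.53 without METTL14 siRNA replicate 1 and -1.83 without METTL14 siRNA replicate 2, so its place in this order rests on the libraries used.

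**Figure D1:**
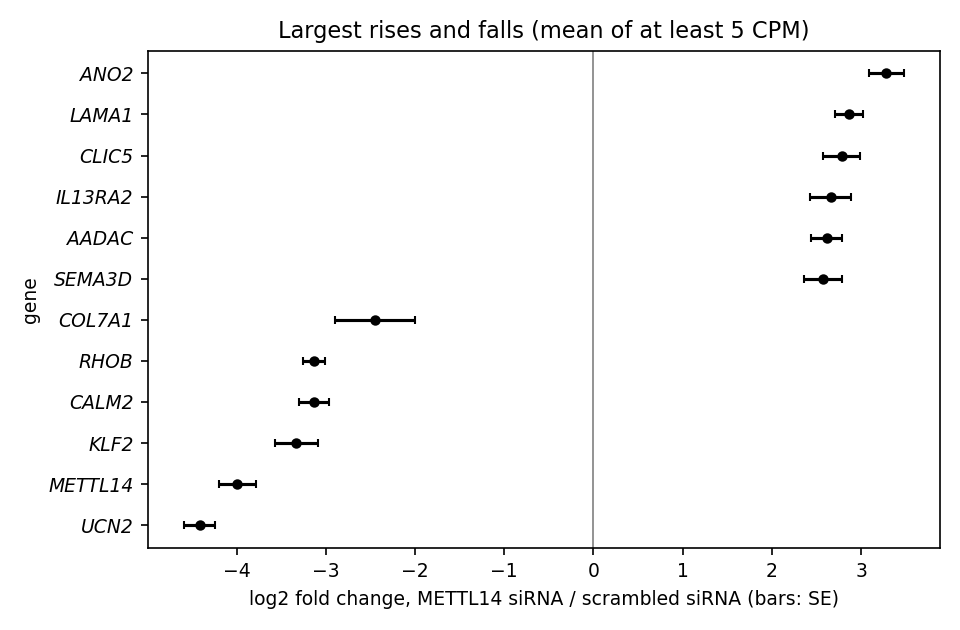
Log2 fold change (x axis, METTL14 siRNA over scrambled siRNA) of the 6 largest rises and the 6 largest falls among genes with a mean of at least 5 CPM (y axis), with horizontal bars for the SE. The falls run from -2.45 for COL7A1 to -4.41 for UCN2 and the rises from 2.57 for SEMA3D to 3.28 for ANO2, and COL7A1 has the widest SE at 0.45.

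In log2 CPM across genes, the Pearson correlation was 0.995 between the scrambled siRNA libraries and 0.990 between the METTL14 siRNA libraries, against 0.973 to 0.977 across groups. All 2986 called genes had groups that did not overlap, as did 8725 of the 14340 tested genes, where chance alone gives 33.3%. The number of calls depended on the library left out, since the spread then comes from the other group's pair alone. The METTL14 siRNA pair lay further apart. Without scrambled siRNA replicate 1, 707 genes were higher and 651 lower; without scrambled siRNA replicate 2, 531 and 525; without METTL14 siRNA replicate 1, 2500 and 2494; and without METTL14 siRNA replicate 2, 2678 and 2601. RPL13AP20 is a processed pseudogene of RPL13A and CALM2 has closely related copies elsewhere in the genome, so their counts are uncertain where reads could be shared. Among the genes named here, the exons of GGCX, HNRNPA2B1, CCNA2, TNFRSF10B and RPS25 overlap those of another tested gene on the opposite strand in GENCODE 29, and the strand setting of the counting is not given in the sources used here. Only GENCODE 29 names were matched, so genes that the files hold under older symbols could be missed. CCND1, RBM15B and CLDN7 overlap LTO1, DCAF1 and ELP5 on the opposite strand. Those names are not among the tested genes, but older symbols for them were not searched. The 3′ UTRs of DUSP1, PDGFD, SEMA3D, TGFB2, CYCS, HMGCS1 and STARD4 carry GAATATA, the heptamer most enriched among genes that rose, and so do those of ITGAV, GINS1 and RBM15B, which fell. GTTGTAC, the heptamer most enriched among genes that fell, is carried by ELAVL1, HNRNPA2B1, ITGAV and GINS1, which fell, and by RELN, which rose.

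The series names 4 genes as altered, and all 4 fell. The TGF-beta effector SMAD3 had a log2 fold change of -1.08 (SE 0.10, adjusted p = 0.000418), from a mean of 280 to 133 CPM, and the G1 cyclin gene CCND1 one of -1.16 (SE 0.10, adjusted p = 0.000343), from 252 to 113 CPM. CCNE1, the cyclin of the G1/S step, went from 31.3 to 13.0 CPM (-1.27, SE 0.14, adjusted p = 0.000924). TGFB1, the ligand itself, was at 40.1 and 38.7 CPM in the scrambled siRNA libraries and at 28.4 and 16.8 CPM in the METTL14 siRNA libraries, a log2 fold change of -0.80 (SE 0.23, adjusted p = 0.0411). The 3′ UTRs of CCND1 and CCNE1 also carry GTTGTAC, and those of SMAD3 and TGFB1 do not. All 4 also passed when adjusted over the list alone, which is not independent evidence since the study chose them on these samples. The list test, camera, gave an adjusted p of 0.00215. It was 0.978 with an estimated correlation, a test on 2 residual degrees of freedom that few lists could pass. The TGFB1 call rests on the choice of libraries and scaling: its log2 fold change was -0.46 without METTL14 siRNA replicate 2 and -1.23 without METTL14 siRNA replicate 1, and its adjusted p was 0.155 without scrambled siRNA replicate 2, 0.0837 with upper-quartile factors and 0.105 with library size only, within a range of 5.06e-12 to 0.155 over 15 alternatives.

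**Figure D2:**
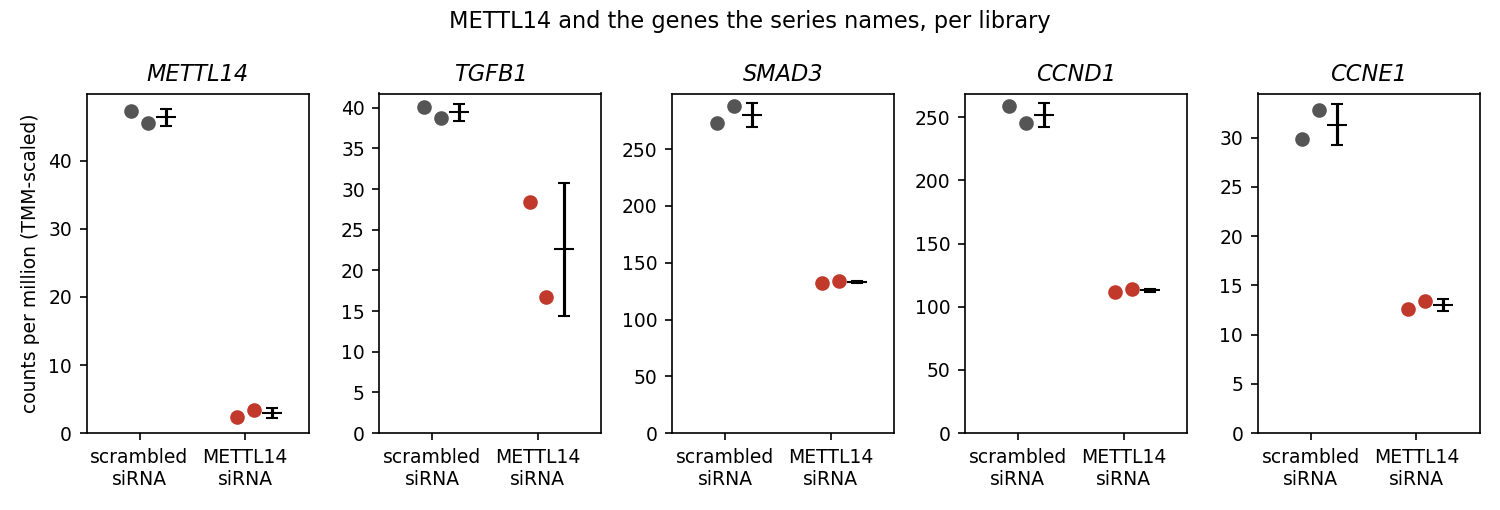
TMM-scaled CPM (y axis, from 0, a separate scale per gene) of METTL14, TGFB1, SMAD3, CCND1 and CCNE1 in each of the 4 libraries (points), with the mean and SD of each group beside them (x axis, group). METTL14 drops from a mean of 46.3 to 2.92 CPM, and the METTL14 siRNA libraries lie at 28.4 and 16.8 CPM for TGFB1 but close together for SMAD3, CCND1 and CCNE1.

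Of 8 other genes listed as m6A writers, 1 rose, METTL16, a methyltransferase outside the METTL3-METTL14 complex that acts on a separate set of RNAs (log2 fold change 0.41, SE 0.11, adjusted p = 0.0294), and 1 fell, RBM15B, an adaptor of that complex (-0.39, SE 0.11, adjusted p = 0.0461). METTL3, the catalytic partner of METTL14, had a log2 fold change of -0.20 (adjusted p = 0.235). Adjusted over the list alone, 1 was higher and 3 were lower. Over all genes, the writers numbered 1 higher and 3 lower with the replicate number as a block. With GC-trend offsets, chosen after the data were seen, they numbered 2 higher and 3 lower. Of 15 m6A erasers and readers, the reader gene YTHDF3 rose (1.03, SE 0.11, adjusted p = 0.000765), while HNRNPA2B1 (-0.63, SE 0.15) and ELAVL1, whose protein binds AU-rich elements (-0.59, SE 0.10), fell; 1 was higher and 3 were lower adjusted over the list alone. Neither list passed camera's test (adjusted p = 0.869 and 0.938). METTL16 had an adjusted p of 0.211 without scrambled siRNA replicate 1 and 0.276 without scrambled siRNA replicate 2, RBM15B one of 0.483 and 0.168 in the same order, and HNRNPA2B1 one of 0.0946 and 0.0622. RBM15B also missed the threshold with upper-quartile factors (0.0597), library size only (0.0717) and no filter on low counts (0.0667).

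TGF-beta pathway components went both ways, with 4 of 26 higher and 12 lower (5 and 13 adjusted over the list alone). LTBP1, which stores latent TGF-beta in the matrix, fell (-1.48, SE 0.10, adjusted p = 0.000203) as SMAD3 did, and the ligand gene TGFB2 rose (1.42, SE 0.10, adjusted p = 0.000226). The list had a median log2 fold change of -0.38 and an adjusted p of 0.0609 in camera. Camera's adjusted p was 0.0358 on voom values, 0.0358 with a filter of 1 CPM in 2 libraries and 0.978 with an estimated correlation. Fry, which compares a list with no change rather than with other genes, gave 0.015, and the 10 alternatives together ran from 0.015 to 0.978. Of 27 genes that TGF-beta signalling is known to induce, 9 rose and 7 fell (11 and 8 adjusted over the list alone; camera adjusted p = 0.938). CTGF and EDN1, which encode connective tissue growth factor and endothelin 1, were among the rises (1.59, SE 0.12; 1.87, SE 0.16). This list's median was -0.03 and its mean 0.22. In the fits without scrambled siRNA replicate 1 and without scrambled siRNA replicate 2, the pathway components numbered 1 and 1 higher and 6 and 4 lower, and the target genes 8 and 5 higher and 5 and 4 lower.

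Of 20 mesenchymal genes, 10 fell, 0 rose and 10 did not pass (11 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.53. The membrane protease gene MMP14 went from 219 to 72.9 CPM (-1.59, SE 0.10, adjusted p = 0.000184), the matrix gene TNC from 723 to 360 CPM (-1.01, SE 0.11) and the intermediate filament gene VIM from 1489 to 713 CPM (-1.06, SE 0.12). The list's adjusted p was 0.000764 in camera, and 0.978 with an estimated correlation. Of 15 epithelial genes, 1 rose and 2 fell, the same numbers as when adjusted over the list alone, with the claudin genes CLDN4 (-1.60, SE 0.24) and CLDN7 (-0.93, SE 0.15) among the falls (camera adjusted p = 0.96). The 1 rise, in the cadherin gene CDH3 (1.25, SE 0.33, mean of 0.906 against 2.16 CPM), had an adjusted p of 0.273 without scrambled siRNA replicate 2 and of 0.0587 with library size only. Epithelial rises numbered 2 without scrambled siRNA replicate 1, 0 without scrambled siRNA replicate 2, 3 without METTL14 siRNA replicate 1 and 3 without METTL14 siRNA replicate 2, where falls numbered 4. Of 37 integrin and extracellular matrix genes, 16 fell and 1 rose (17 and 2 adjusted over the list alone), with a median of -0.49. The falls included the integrin gene ITGAV (-1.54, SE 0.12) and the metalloproteinase inhibitor gene TIMP3 (-1.28, SE 0.12). This list had a camera adjusted p of 0.000764, and 0.978 with an estimated correlation, and 4 and 6 rises without scrambled siRNA replicate 1 and without METTL14 siRNA replicate 2. Mesenchymal genes lower numbered 5 without scrambled siRNA replicate 1, 3 without scrambled siRNA replicate 2, 14 without METTL14 siRNA replicate 1 and 11 without METTL14 siRNA replicate 2.

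Of 37 mitosis genes, 27 fell, 0 rose and 10 did not pass (32 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -0.54. The kinesin gene KIF2C fell from 168 to 85.9 CPM (-0.97, SE 0.10, adjusted p = 0.000778), the cyclin gene CCNA2 from 238 to 115 CPM (-1.05, SE 0.13) and the spindle checkpoint gene MAD2L1 from 224 to 106 CPM (-1.08, SE 0.14). The list's camera adjusted p was 1.3e-09. With an estimated correlation, which was 0.585 between its genes, it was 0.978. That test rests on 2 residual degrees of freedom, so the part of the correlation in this was not separated. Falling members numbered 13 without scrambled siRNA replicate 1, 10 without scrambled siRNA replicate 2, 30 without METTL14 siRNA replicate 1 and 34 without METTL14 siRNA replicate 2. Among the 37 DNA replication genes, 2 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.162), among them GINS1 (-1.09, SE 0.15) and RFC5 (-0.71, SE 0.12), with 4, 2, 10 and 12 falls and 0, 0, 5 and 4 rises in the same order of libraries left out. Of 22 G1/S cyclins, kinases and inhibitors, 3 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.95). The rises included MYC, a transcription factor gene that promotes growth (1.26, SE 0.10, adjusted p = 0.000274), and the falls CCND1 and CCNE1. The list's median was 0.09 and its mean -0.07, and its rises numbered 1, 1, 3 and 6 in that order of libraries.

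**Figure D3:**
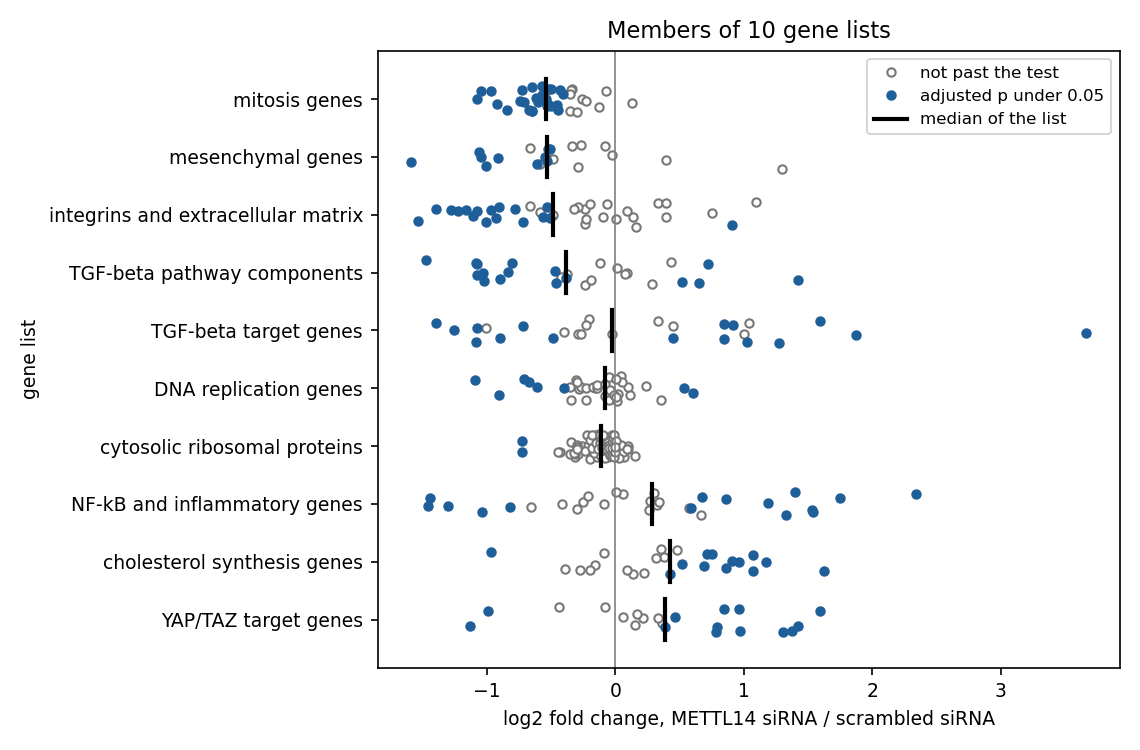
Log2 fold change (x axis, METTL14 siRNA over scrambled siRNA) of each tested member of 10 gene lists (y axis), filled where the adjusted p was under 0.05, with a black bar at each list's median. The medians run from -0.54 for mitosis genes to 0.42 for cholesterol synthesis genes, and the TGF-beta target gene at 3.66 is PDGFB, named here after its value was seen.

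YAP/TAZ target genes, the readout of the Hippo pathway, had 11 of 21 members higher and 2 lower (11 and 3 adjusted over the list alone) and a median log2 fold change of 0.39. CTGF went from 626 to 1887 CPM (1.59, SE 0.12, adjusted p = 0.000255), and TGFB2 and IGFBP3, a binding protein of insulin-like growth factors (1.31, SE 0.12), rose too. Cholesterol synthesis genes had 12 of 25 members higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 0.42. HMGCS1, which makes the HMG-CoA that the pathway starts from, went from 108 to 334 CPM (1.62, SE 0.17, adjusted p = 0.000722), and STARD4, a sterol carrier (1.07, SE 0.12), rose with it. Cholesterol synthesis genes lower numbered 3 without METTL14 siRNA replicate 1. Without scrambled siRNA replicate 2, 8 cholesterol synthesis genes were higher and 1 YAP/TAZ target was lower. The camera adjusted p was 0.000961 for YAP/TAZ targets and 0.00172 for cholesterol synthesis, and 0.978 for both with an estimated correlation. Wnt target genes were mixed, with 5 of 16 higher and 4 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.95), among them the Wnt antagonist gene DKK1, which rose (1.17, SE 0.10). The Wnt list's median was -0.23 and its mean 0.08, and it had 3 higher and 2 lower without scrambled siRNA replicate 1 and 3 and 1 without scrambled siRNA replicate 2.

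Of 24 p53 target genes, 1 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.938), and of 30 apoptosis regulators, 7 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.938). The line carries mutant p53, so the p53 list may not read a normal p53 response. TNFRSF10B, a death receptor gene in both lists, went from 414 to 176 CPM (-1.23, SE 0.10, adjusted p = 0.000287). CYCS, which encodes cytochrome c (1.68, SE 0.16), and BIRC3, an inhibitor of apoptosis (1.19, SE 0.11), rose. Without scrambled siRNA replicate 1 as well as without scrambled siRNA replicate 2, 3 apoptosis regulators were higher and 2 lower, and of the p53 targets 0 were higher and 1 lower. Without METTL14 siRNA replicate 1 the p53 targets numbered 5 higher and 6 lower, and without METTL14 siRNA replicate 2, 5 and 4, with 8 apoptosis regulators lower in the latter.

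Markers of other cell types were read as a check of the cultures. Of 13 luminal breast epithelial markers, 2 rose and 2 fell, and the hormone receptor gene PGR went from a mean of 3.95 to 11.8 CPM (1.58, SE 0.19, adjusted p = 0.00137) and AGR2 from 1.85 to 5.08 CPM (1.45, SE 0.31), while TOB1 was lower (-0.89, SE 0.16). Of 5 tested fibroblast markers, COL3A1 rose, from 0.313 to 1.26 CPM (2.01, SE 0.35, adjusted p = 0.00576), and of 5 tested blood cell markers, CD68 fell, from 268 to 177 CPM (-0.60, SE 0.11). With the replicate number as a block, 3 blood cell markers were lower and 0 higher, and 2 fibroblast markers were higher and 0 lower. Luminal markers then numbered 4 higher and 2 lower. Adjusted over the list alone, the calls were 2 higher and 2 lower for luminal markers, 1 higher for fibroblast markers and 2 lower for blood cell markers, and no marker list passed camera (adjusted p = 0.86, 0.79 and 0.623). AGR2 and TOB1 had adjusted p of 0.119 and 0.0638 without scrambled siRNA replicate 2, and CD68 had 0.102 without scrambled siRNA replicate 1. Of 14 replication-dependent histone genes and 4 small structured RNAs, which can show how RNA was selected, 0 passed edgeR's test of the groups with no block, also when adjusted over the list alone (camera adjusted p = 0.938 and 0.965). At an unadjusted p under 0.05 there were 4 histone genes and 1 small RNA, and DESeq2 called 1 and 0 and limma-voom 0 and 0. Histone calls did appear in other edgeR fits, with 0 higher and 2 lower without METTL14 siRNA replicate 1, 4 and 1 without METTL14 siRNA replicate 2, and 1 and 1 with GC-trend offsets, which were chosen after the data were seen. Of the small RNAs, 1 was lower without METTL14 siRNA replicate 1. HIST1H2BD and HIST1H2BK, the histone genes of smallest unadjusted p, had log2 fold changes of -0.55 (SE 0.18) and 0.33 (SE 0.11). HIST1H2BD had an adjusted p of 0.0048 without METTL14 siRNA replicate 1 and HIST1H2BK one of 0.000236 without METTL14 siRNA replicate 2 and 0.0497 with no filter on low counts. With GC-trend offsets they had 0.025 and 0.0182. SCARNA6 and RPPH1, the small RNAs of smallest unadjusted p, had log2 fold changes of 1.53 (SE 0.64) and -0.33 (SE 0.39).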

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

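Reads outside annotated genes, which no comparison used, made up 13.8% ± 0.103 (SD, n = 2) of all reads in the METTL14 siRNA libraries, above the 13.3% ± 0.0711 (SD, n = 2) of the scrambled siRNA libraries. Reads at more than 1 place were lower, at 14.2% ± 0.0624 against 14.7% ± 0.02 (SD, n = 2 each). With 2 libraries per group, an exact permutation test cannot give a p under 0.333 for either share.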

How the results depend on the processing

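The alternatives with GC offsets, or without genes that carry a heptamer, were chosen after the result was seen. Over the alternatives, 0 of 92 named genes changed direction. Of the 30 lists, 11 did so in 26 fits, 4 of them with fry, all without a call before or after (adjusted p from 0.356 to 0.991). Named genes kept their direction and side of the threshold in 1323 of 1376 alternative fits, 43 lost the call and 10 gained it; lists kept both in 250 of 298, with 17 calls lost and 5 gained. Genes higher and lower moved by more than 1.5 times from 1524 and 1462 to 741 and 662 at an adjusted p under 0.01, and to 382 and 300 against a fold change of 1.5, both stricter by construction. With 1 library left out they ran from 531 to 2678 and from 525 to 2601; the cause was not tested. TGFB1 ran from -1.23 to -0.46 with 1 library left out, and lost its call at -0.79 with upper-quartile factors and at -0.79 with library size only; the cause was not tested. With no filter on low counts, 1866 genes were higher and 1386 lower. Without genes that carry GAATATA in the 3′ UTR, 980 of the higher genes were left, fewer by construction, and without carriers of GTTGTAC, 1168 of the lower genes. The labels do not say that a replicate number marks a shared culture or day. Same-numbered libraries' deviations from their group means correlated at 0.375 across genes, over 2 pairs; with the replicate block, 2871 genes were higher and 3070 lower, and with GC-trend offsets as well, 3712 and 3872. Of the histone genes, 3 were higher and 1 lower with the block (4 and 1 with both), with an adjusted p of 0.000318 for HIST1H2BD and 0.00152 for HIST1H2BK, and of the cytosolic ribosomal protein genes 15 were lower and 0 higher (27 and 2 with both). Counts of other lists moved too. DNA replication genes lower went from 6 to 14 with the block and 13 with GC-trend offsets, and nuclear oxidative phosphorylation genes lower from 3 to 12 and 14. NF-kB and inflammatory genes higher went from 10 to 16 and 16. In some lists the larger side changed with the block. Interferon-stimulated genes went from 4 higher and 7 lower to 10 and 8, p53 targets from 1 and 3 to 5 and 4, and epithelial genes from 1 and 2 to 5 and 4. GC-trend offsets alone gave 2808 and 2945, of which 1523 and 1447 were shared with the main calls. GC content followed the difference between the libraries of a group (Spearman's rho across genes 0.516 for scrambled siRNA and 0.682 for METTL14 siRNA). Among genes with a transcript, the correlation of these differences went from 0.417 to 0.119 once GC content and length were regressed out, between the bounds of 0.1 and 0.19 set beforehand, so a GC trend as the whole source stays open. At this depth and with 2 libraries per group, 36.7% of simulated 1.5-fold changes were called. The simulation changed a far smaller share of genes than the 20.8% called in the data. An adjusted p depends on that share, so the percentage for these data may differ. Depth, the number of libraries and the share of changed genes were not varied, so their parts in the simulated percentage were not separated.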

Other observations

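Of 30 NF-kB and inflammatory genes, 10 rose and 5 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.145). The collagenase gene MMP1 went from a mean of 2356 to 11919 CPM (log2 fold change 2.34, SE 0.18, adjusted p = 0.000257 in edgeR), the cytokine gene IL6 from 43.1 to 125 CPM (1.53, SE 0.11) and TNFAIP3, an inhibitor of NF-kB, from 55.3 to 139 CPM (1.33, SE 0.10). The list's adjusted p was 0.0468 without scrambled siRNA replicate 2 and ranged from 0.0409 to 0.98 over 10 alternatives, and its genes lower numbered 3 without that library. Of 36 interferon-stimulated genes, 4 rose and 7 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.921). IFIT2 (-1.67, SE 0.14), IFIT1 (-1.33, SE 0.13) and IFIT3 (-0.82, SE 0.11), related genes induced by interferon, were among the falls. As a whole the list had a median log2 fold change of 0.13 and a mean of -0.07. The interferon-stimulated genes higher numbered 0 both without scrambled siRNA replicate 1 and without scrambled siRNA replicate 2, with 6 and 4 lower, and 9 without METTL14 siRNA replicate 1 and also without METTL14 siRNA replicate 2. Immediate early and AP-1 genes split into 6 higher and 10 lower of 32 (the same numbers adjusted over the list alone; camera adjusted p = 0.444), with DUSP1 at 2.52, KLF2 at -3.33 and the transcription factor gene KLF6 at -1.35 (SE 0.10). Of 34 hypoxia and glycolysis genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.938). The angiogenic factor gene VEGFA went from 186 to 54.7 CPM (-1.77, SE 0.10), HK2, which encodes hexokinase, from 240 to 121 CPM (-0.99, SE 0.10), and the peptide hormone gene ADM rose (1.59, SE 0.17). Without scrambled siRNA replicate 1 as well as without scrambled siRNA replicate 2, 2 hypoxia and glycolysis genes were higher and 3 lower, and 10 were higher without METTL14 siRNA replicate 2.

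Of 69 cytosolic ribosomal protein genes, 2 fell and 0 rose (1 and 0 adjusted over the list alone), namely RPL13A (-0.73, SE 0.11) and RPS25 (-0.73, SE 0.16). The list's median log2 fold change was -0.11, with a camera adjusted p of 0.0495, and 0.978 with an estimated correlation. It missed the threshold without scrambled siRNA replicate 1 (0.191), without scrambled siRNA replicate 2 (0.0612), without METTL14 siRNA replicate 1 (0.114) and without METTL14 siRNA replicate 2 (0.0558), where 1, 3, 13 and 14 of its genes were lower and 0, 0, 1 and 4 higher. With GC-trend offsets, chosen after the data were seen, 9 were lower and 1 higher. RPS25 had an adjusted p of 0.105 without scrambled siRNA replicate 1. Of 47 nuclear oxidative phosphorylation genes, 3 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.287), with ATP5J, a subunit of ATP synthase, at -1.48 (SE 0.14), and 1, 1, 11 and 13 fell and 0, 0, 3 and 1 rose in the same order of libraries left out. Of 34 amino acid and ER stress genes, 6 rose and 5 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.79), with 2, 1, 11 and 11 higher in that order of libraries and 0, 0, 5 and 8 lower. The cystine transporter gene SLC7A11 rose (0.70, SE 0.11, adjusted p = 0.0872 without scrambled siRNA replicate 1), as did CHAC1 (2.30, SE 0.39, adjusted p = 0.0513 without scrambled siRNA replicate 2). Of 10 long nuclear RNAs, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.976), and NEAT1, which builds paraspeckles, went from 476 to 254 CPM (-0.91, SE 0.12). Long nuclear RNAs numbered 0 higher and 1 lower without scrambled siRNA replicate 1 and without scrambled siRNA replicate 2, and 2 and 4 without METTL14 siRNA replicate 2. Of 13 genes of the RNA interference machinery, 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.623). The fall was in TNRC6A, a partner of Argonaute (-0.60, SE 0.10), which had an adjusted p of 0.0759 without scrambled siRNA replicate 1, and a rise was in EIF2C2, the Argonaute 2 gene (0.58, SE 0.16), which had 0.284 without scrambled siRNA replicate 2, 0.0696 with upper-quartile factors and 0.0919 with library size only, in a range of 1.81e-10 to 0.284 over 15 alternatives. EIF2C2's log2 fold change was 0.34 without METTL14 siRNA replicate 1. Members of this list higher numbered 1, 0, 3 and 4 in the order of libraries given above, and those lower 0, 1, 1 and 2.

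A first hypothesis concerns the genes that fell, and its heptamer and the test adjusted for 3′ UTR length and GC content were chosen after the scan was seen. GTTGTAC led all 16384 heptamers among 3′ UTRs of genes that fell, in 294 of 1389 (21.2%) against 5.75% of other genes (Bonferroni p = 2.87e-66 in an exact hypergeometric test). Its odds ratio was 4.11 (95% interval 3.51 to 4.82) after adjustment for 3′ UTR length and GC content, which argues against these as the whole source (the lower limit is 3.51), and the next of 420 heptamers of the same composition reached 1.55. The median log2 fold change of genes with it in the 3′ UTR, minus that of genes with it upstream only, was -0.0863 (permutation p = 0.0103). This argues against an effect of equal size anywhere in the transcript. Genes with it upstream only, METTL14 among them, still had a median of -0.0860, against 0.00083 for genes without it. Of these upstream carriers 15.9% were called lower, against 8.84% of genes without it, so a smaller upstream effect stays open. A candidate explanation is pairing of the METTL14 siRNA's seed with other mRNAs: METTL14 mRNA holds GTTGTACA once, upstream of its 3′ UTR, but so, anywhere in the transcript, do 8.24% of tested transcripts of similar length, and the siRNA's sequence was not used here. The scanned heptamer GTTGTAC stood in 17.8% of those transcripts. METTL14 mRNA also holds GAATATA, the heptamer most enriched among genes that rose, upstream of its 3′ UTR. METTL14 loss itself stays open and untested, since only 1 siRNA and no m6A map were used.

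Direct seed pairing at these heptamers in the 3′ UTR would cover only part of the genes that fell. Indirect effects of such pairing were not tested. Of the 1389, 828 (59.6%) had neither GTTGTAC nor TTGTACA in the 3′ UTR, and among those the hexamer core was enriched with an odds ratio of 1.24 (95% interval 1.04 to 1.47), so seed pairing may reach a few of them. None of the 10 largest falls carried GTTGTAC in the 3′ UTR, and neither did any of the 27 mitosis genes that fell. Only 1 of the 37 mitosis genes carried it at all, so its absence from those that fell says little. Of the genes chosen by the naming rule, METTL14 aside, 13 of the 48 with an annotated 3′ UTR that fell carried it, among them CCND1, CCNE1, ELAVL1, HNRNPA2B1, ATP5J, ITGAV, HK2, GINS1, RPL13A and TNRC6A. So did 3 of the 35 that rose, RELN (2.47), ADM (1.59) and SLC7A11 (0.70), while SMAD3 and TGFB1 did not.

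A second hypothesis concerns the genes that rose; its heptamer was picked from the scan. GAATATA stood in the 3′ UTRs of 544 of 1433 genes that rose (38.0%) against 12.8% of others. Risen genes had longer 3′ UTRs (a median of 2297 bases, against 1580 for fallen and 1252 for other genes), but the odds ratio adjusted for length and GC content was 2.41 (95% interval 2.11 to 2.76), so these do not account for all of it, and the next of 105 heptamers of the same composition reached 1.84. Pairing of the scrambled siRNA with mRNAs in the control cells, which would make those genes seem to rise, may contribute. Of the genes chosen by the naming rule, 11 of the 35 that rose carried the heptamer, among them MMP1, DUSP1, HMGCS1, STARD4, CYCS, TGFB2, PDGFD, SEMA3D, EIF2C2 and SLC7A11, while CTGF, IL6 and MYC did not. It was also carried by 6 of the 48 that fell, among them IFIT1 (-1.33), ITGAV (-1.54), GINS1 (-1.09) and RBM15B (-0.39). An effect of METTL14 loss on these genes remains open, and a second control or a METTL14 rescue would separate the 2. Another METTL14 siRNA set against the same scrambled siRNA would not.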
